A study of Mus musculus with 6 samples.

How the data were processed

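Gene expression was measured with Affymetrix mouse gene arrays on total RNA from whole retina of male mice at postnatal day 17. The labels give 3 Atrx conditional knockout samples, which carry a Cre transgene and a floxed Atrx allele, and 3 wildtype littermates without Cre. Each sample pooled the retinas of both eyes, and cDNA was made from 100 ng of RNA per the labels' protocols. The labels state that the lens was taken out before the retina was removed. All knockout animals carry the transgene and no control animal does, so an effect of the transgene and an effect of losing Atrx cannot be separated in this design.

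The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA corrects the background, normalizes arrays by quantiles and summarises the probes of a probe set. The version of RMA, the software that ran it and the genome build behind the array annotation are not given in the sources used here. The 6 arrays hold 41345 probe sets each, with array medians between 5.57 and 5.64. Quantile normalization makes array distributions alike, so a change in the total amount of RNA per cell would not be seen, and small folds of dim probe sets are compressed by background signal.

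Of the 41345 probe sets, 23521 had exactly 1 gene symbol in the platform annotation, 1814 had several and 16010 had none in the annotation used here. Genes were named only from probe sets with 1 symbol. Of these, 23328 had a gene identifier that matched the RefSeq gene table of assembly GRCm38.p6, which was used for gene names and spans only. A probe set was tested if its log2 value was at least 5 on at least 3 of the 6 arrays, and a gene with several such probe sets was represented by the one with the highest mean over all 6 arrays. This left 15619 genes, of which 678 had several probe sets. Probe sets without a single symbol were not used in the comparison of genes.

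Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, genotype as the only term, 2-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes come from this fit unless another setting, an array left out or an adjustment over a list alone is named. Log2 changes are knockout minus wildtype, given with limma's moderated standard error (SE), and group values are means with the standard deviation (SD) of 3 arrays. The number of arrays limits the precision: the median SE was 0.095 and the median 95% interval reached 0.22 to each side of the estimate. With 3 arrays against 3, the smallest p of an exact permutation test is 0.1.

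Before the data were examined, 45 gene lists were fixed (cell class markers, receptors, channels, stress pathways and chromatin partners), together with the test, the alternatives and the rule for named genes. A total of 44 lists had at least 3 tested members; the red blood cell list did not. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 44 lists; 1 of these lists is not reported here. Camera with an estimated correlation and fry were the alternatives. Of 715 list entries 587 were tested, 49 were too dim and 79 had no probe set with that single symbol; the last are not analysed here. Members were also counted with p-values adjusted over the list alone. The named genes are Atrx, the 12 called genes with the largest rise and the 12 with the largest fall whose 3 knockout values all lay on one side of the 3 wildtype values, without predicted or unnamed loci and small RNAs, and up to 4 members of each described list with the smallest unadjusted p. Other genes named in the closing part were chosen after their values were seen.

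Alternatives fixed beforehand were no filter on dim probe sets, a floor of 6, a second quantile normalization, centring of arrays, an intensity trend with robust spread, array weights, the replicate number as a block, the mean of a gene's probe sets, each array left out in turn, a test without pooled spread, thresholds with a fold of at least 1.5, and all probe sets. Leaving out the 2 arrays rich in lens RNA, and the lens list mean as a covariate, were added after seeing the data. The procedure was tested on simulated data for the same 15619 genes and 3 against 3 arrays: 38 of 100 genes changed by 0.5 and 94 of 100 changed by 1 on the log2 scale were called, with 4 false calls, and the 1 shifted list of 30 was called with no other. The simulated noise was independent between genes and held no lens-rich arrays. The simulation therefore does not show how often lists of correlated genes would be called falsely. Figures were drawn with matplotlib 3.10.9.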

Results

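Whole retinas of 3 male mice with a Cre-mediated conditional knockout of Atrx, a chromatin remodeller, and of 3 wildtype littermates were compared at postnatal day 17. By the series' design text this age is the peak of amacrine and horizontal cell degeneration in these mice, and the comparison asks which genes differ at that time. Each array held 41345 probe sets, and array values correlated with Pearson's r between 0.975 and 0.993 across the 15619 genes tested. The first principal component (35.8% of the variance) set knockout 2 and wildtype 1 apart from the other 4 arrays, and the second (26.8%) separated the genotypes.

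Slc5a7 and Vip, genes of amacrine cells, were among those that fell in knockout retina. Slc5a7, the high-affinity choline transporter, fell from 7.01 ± 0.17 to 5.46 ± 0.26 (mean ± SD of log2 values, n = 3 per group), a 2.94-fold difference. Vip, which encodes vasoactive intestinal peptide, fell from 8.06 ± 0.08 to 6.85 ± 0.31, a 2.31-fold difference. In the other direction Gulo, the enzyme of the last step of ascorbate synthesis, rose from 8.35 ± 0.28 to 9.71 ± 0.28. Abcd4, a lysosomal transporter, rose from 6.94 ± 0.11 to 8.28 ± 0.23. The call of Gulo was lost without knockout 3 (adjusted p = 0.056) or wildtype 2 (0.081), and that of Vip without knockout 1 or wildtype 2 or 3 (0.053 to 0.065); those of Slc5a7 and Abcd4 held without any single array.

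Atrx itself had a mean of 8.49 ± 0.20 in knockout and 9.02 ± 0.16 in wildtype retina (n = 3 per group), a log2 change of -0.53 (SE 0.12). The 3 knockout values were 8.42, 8.72 and 8.33, and each lay below the wildtype values of 9.04, 8.86 and 9.17. The difference missed the threshold over all genes (adjusted p = 0.115), and the exact permutation p was 0.1, the smallest that 3 against 3 allows. Where the probes lie against the floxed part of the gene was not examined here, so how much of a loss this probe set can show is unknown. With an intensity trend and robust spread the adjusted p was 0.039.

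In all, 129 of 15619 genes differed in limma's test, 75 of which rose and 54 fell. For all 129 the 3 knockout values lay on one side of the 3 wildtype values. Over all tested genes this held for 3172 (20.3%, against 10% by chance). Their median fold was 1.63, and 91 differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 2107 genes, against 781 expected by chance. In the other splits of the arrays into 3 and 3, which mix the genotypes, the count ran from 315 to 1217. Among the 129 were 15 unnamed loci or small RNAs, 12 of which rose.

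The largest rises were those of Tceanc2 (log2 change 1.81, SE 0.098), Bst1 (1.49, SE 0.19), Tex15 (1.44, SE 0.15), Gulo (1.35, SE 0.17), Abcd4 (1.34, SE 0.12) and Tmem26 (1.27, SE 0.15). Bst1 encodes an enzyme of the ADP-ribosyl cyclase family, and Tex15 is a gene of male meiosis. Next came Apela (1.25), a ligand of the apelin receptor, Otop3 (1.18), a proton channel, Zfp949 (1.17), Psd2 (1.17), Cdcp3 (1.16) and Fcamr (1.02). Their adjusted p-values ran from 0.00081 for Tceanc2 to 0.030 for Fcamr. Tceanc2 has a second, dimmer probe set with a log2 change of -0.13, so its probe sets disagree.

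The largest falls were those of Slc5a7 (log2 change -1.56, SE 0.14), the adenylate kinase Ak5 (-1.54, SE 0.10), Rasgrf2 (-1.25, SE 0.11), Vip (-1.21, SE 0.15), the bestrophin Best2 (-1.20, SE 0.14) and Ramp3 (-1.12, SE 0.081). The knockout mean of Ak5, 4.99, lay under the log2 floor of 5, where background limits the fold seen. Tac2, which encodes neurokinin B, changed by -1.11 and Rasgrp1 by -1.03. Rasgrf2 and Rasgrp1 both encode activators of Ras. Cdh6 changed by -1.03, the transcription factor Mef2c by -0.93, Olfm3 by -0.93 and Cbln4, a secreted synaptic organiser, by -0.88. Adjusted p-values ran from 0.0013 for Ak5 to 0.032 for Rasgrp1. The second probe set of Mef2c had a log2 change of 0.17.

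Of these 24 genes, 12 passed the threshold whichever single array was left out, and 7 of the 12 had risen. Without wildtype 2 the call was lost for 10 genes (adjusted p from 0.057 to 0.107), and likewise for 10 without wildtype 3 (0.051 to 0.141). Without knockout 1, 2 or 3 it was lost for 4 (0.053 to 0.114), 2 (0.056 to 0.070) and 3 (0.056 to 0.072), and without wildtype 1 for 3 (0.054 to 0.094). The total of 129 became 58, 141 and 78 without knockout 1, 2 and 3, and 62, 25 and 38 without wildtype 1, 2 and 3.

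**Figure D1:**
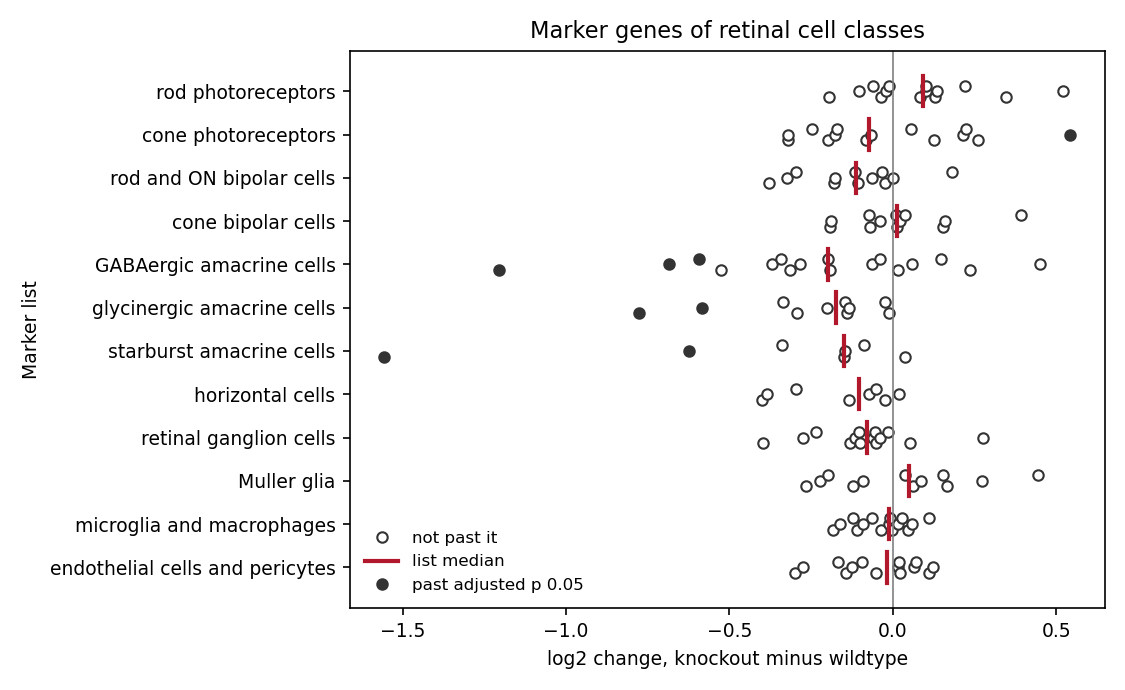
Log2 change (knockout minus wildtype, horizontal axis) of each tested marker gene of 12 retinal cell class lists, with filled points past an adjusted p of 0.05, open points not past it, and a red bar at the list median. Medians of the 3 amacrine lists lie between -0.20 and -0.15, and the lowest point is Slc5a7 at -1.56.

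The 3 lists of amacrine cells, interneurons of the inner retina, fell with the preset correlation. These calls were lost with an estimated correlation: adjusted p = 0.45 with an estimated correlation for the glycinergic and starburst lists, and adjusted p = 0.57 with an estimated correlation for the GABAergic list. For the starburst list that estimate, 0.0031, was below the preset 0.01, so a higher correlation does not account for its lost call. The ganglion cell list, with a negative estimate of -0.031, also went from an adjusted p of 0.064 to 0.57. A call lost in this version of camera is therefore not shown to come from correlation between genes. In the glycinergic list all 10 tested members had negative log2 changes (adjusted p = 0.00021); Slc17a8, a vesicular glutamate transporter, fell (-0.78, SE 0.10), as did the glycine transporter Slc6a5 (-0.58, SE 0.10), and 8 members were not called. In the starburst list, cells that release acetylcholine, Slc5a7 fell together with Chat (-0.62, SE 0.081), which makes acetylcholine, and 5 of 7 members were not called (list adjusted p = 0.0017). Slc18a3 of the same list had a log2 change of -0.34 and Slc10a4 of -0.15. In the GABAergic list Vip, Gad1 (-0.68, SE 0.095) and Nos1 (-0.59, SE 0.098) fell and 14 of 17 members were not called (list adjusted p = 0.0021). Tfap2b, an amacrine transcription factor, had a log2 change of -0.52 (adjusted p = 0.104). Adjusted over the list alone, 4 glycinergic, 2 starburst and 5 GABAergic members fell, and 1 GABAergic member, Npy (0.45), rose. Slc5a7 passed the threshold without any single array. The calls of Chat and Gad1 were lost without knockout 1 or 3 or wildtype 2 or 3 (adjusted p from 0.055 to 0.107), those of Nos1, Slc17a8 and Slc6a5 without any array but knockout 2 (0.058 to 0.197), and that of Vip without knockout 1 or wildtype 2 or 3 (0.053 to 0.065).

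**Figure D2:**
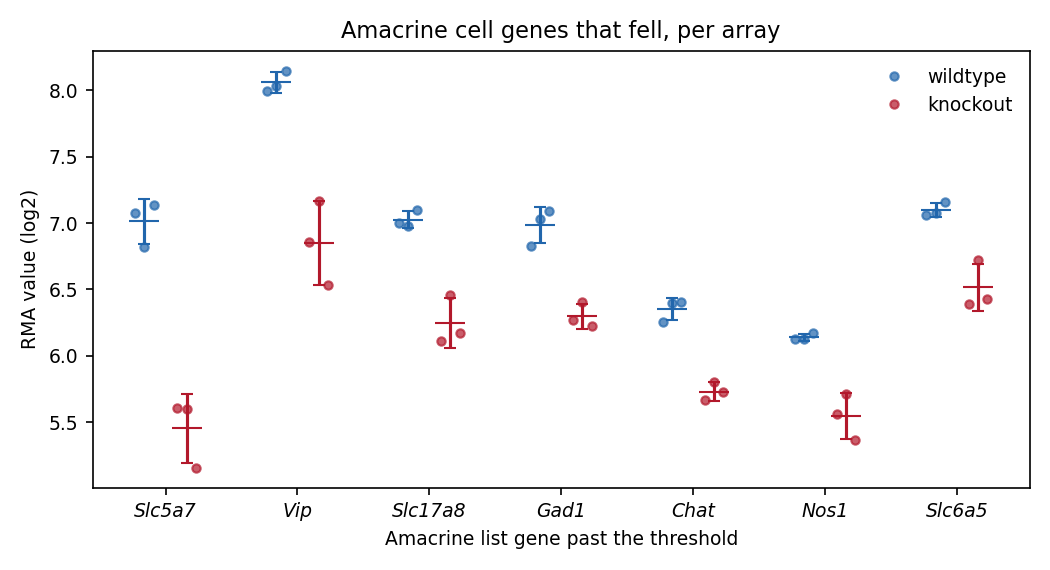
RMA log2 values (vertical axis) of the 7 amacrine list genes that fell, with a point per array, a bar at the mean and error bars of 1 SD (n = 3 per group). Every knockout point lies below every wildtype point of its gene; the knockout values of Slc5a7 lie between 5.16 and 5.61.

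The horizontal cell list also fell (adjusted p = 0.027; adjusted p = 0.57 with an estimated correlation). None of its 8 tested members was called, and 7 had negative log2 changes, most of them small (list median -0.10). Onecut1, a transcription factor of horizontal cells, had a log2 change of -0.38 (SE 0.070, adjusted p = 0.055), Prox1 of -0.40 and Onecut3 of -0.30; these 3 fell when adjusted over the list alone. The list missed the threshold without knockout 2 (adjusted p = 0.069), knockout 3 (0.152) or wildtype 3 (0.054), and without knockout 2 and wildtype 1 together (0.057), which were rich in lens RNA.

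Among the other cell classes no list passed the threshold with the main settings on all 6 arrays. Rod photoreceptor markers had a median log2 change of 0.09 (list adjusted p = 0.168), with Samd7 at 0.52 (adjusted p = 0.055) and Gngt1 at 0.35; both rose when adjusted over the list alone. In the cone list the channel subunit Cngb3 rose (0.54, SE 0.095, adjusted p = 0.049), and the call was lost without any one of the 6 arrays (adjusted p from 0.067 to 0.231). The cone genes Opn1sw and Rxrg each had a log2 change of -0.32, and adjusted over the list alone 3 cone genes fell and 1 rose. Rod and ON bipolar cell markers (list adjusted p = 0.064, and 0.033 without wildtype 1) included Tpbg at -0.30 and Prkca at -0.38, and ganglion cell markers (0.064) included Nefh at -0.40, the only ganglion cell gene past the threshold adjusted over the list alone. Both of these lists passed, downward, with a second quantile normalization (adjusted p = 0.047 for each) and with an intensity trend (0.039 and 0.045). Cone bipolar cells (0.972), Muller glia (0.750), microglia and macrophages (0.626), endothelial cells and pericytes (0.464), oligodendrocytes (0.744) and cornea (0.168) had no called member. In the Muller glia list Abca8a was at 0.44 (adjusted p = 0.066).

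Lens genes were high on 1 array of each group. The mean of 14 lens genes was 10.02 on knockout 2 and 11.26 on wildtype 1, against 5.61 to 6.06 on the other 4 arrays, and Cryaa, an abundant crystallin, reached 12.68 and 13.36 there. The lens list was not called between genotypes (log2 difference -0.34, adjusted p = 0.574), although the list passed the threshold upward without wildtype 1 (0.0040). No lens gene was among the 129. Without these 2 arrays, an alternative chosen after seeing the data, 36 genes were called. Of the 129, 28 passed the threshold. All 129 kept their direction, which was certain beforehand because none of their knockout and wildtype values overlapped. Markers of retinal pigment epithelium varied between arrays as well, with list means from 8.58 on knockout 1 to 9.77 on wildtype 2 (list adjusted p = 0.306; adjusted p = 0.82 with an estimated correlation). That list passed the threshold, downward, without knockout 3 (adjusted p = 0.049), without wildtype 1 (0.0042) and without the 2 lens-rich arrays (0.0077), and reached 0.984 in another of its 18 alternatives.

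**Figure D3:**
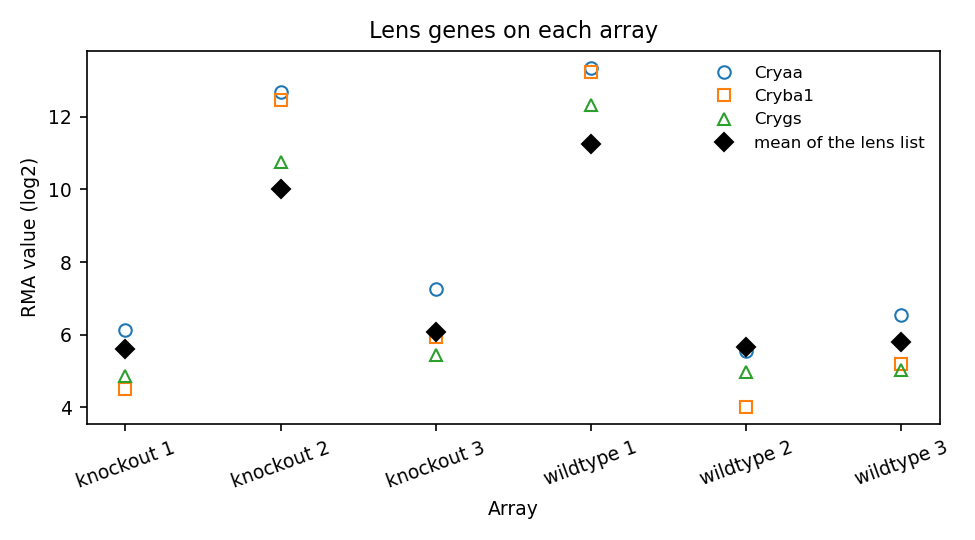
RMA log2 values (vertical axis) of 3 crystallin genes and the mean of the lens list on each of the 6 arrays. Knockout 2 and wildtype 1 have list means of 10.02 and 11.26, and the other 4 arrays lie at or below 6.06.

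Among the synaptic lists, ionotropic and metabotropic glutamate receptors fell (adjusted p = 0.015; adjusted p = 0.68 with an estimated correlation), with 17 of 22 members below 0 and none called. Grm2 had a log2 change of -0.47 and Gria1 of -0.38, and both fell when adjusted over the list alone; Grin2a was at -0.58 and Grm8 at -0.40. The list missed the threshold without knockout 1 (adjusted p = 0.069), knockout 3 (0.126) or wildtype 3 (0.054). Voltage-gated potassium channels fell (adjusted p = 0.0068; adjusted p = 0.57 with an estimated correlation), with Kcnq3 at -0.44, Kcnh1 at -0.50, Kcnd3 at -0.38 and Kcnh7 at -0.41, the 4 members that fell adjusted over the list alone. Genes of synaptic vesicle release fell (adjusted p = 0.0068; adjusted p = 0.68 with an estimated correlation), with Pclo at -0.40, Sv2a at -0.32 and Syn2 at -0.35, none of the 22 being called or past the threshold adjusted over the list alone; the list missed the threshold without wildtype 3 (adjusted p = 0.054). In the GABA and glycine receptor list (adjusted p = 0.275) Gabrr3, a receptor subunit of the rho class, rose (0.59, SE 0.076), also when adjusted over the list alone, and the call was lost without knockout 1 or 3 or wildtype 2 or 3 (adjusted p from 0.052 to 0.093). Calcium channels (adjusted p = 0.053), sodium channels (0.744) and synaptic adhesion (0.327) had no called member. The calcium channel list passed, downward, in 10 of 18 alternatives. Its adjusted p was 0.0023, 0.031 and 0.033 without knockout 2, wildtype 1 and wildtype 2. It was 0.021 with a log2 floor of 6, 0.0021 without both lens-rich arrays and 0.68 with an estimated correlation. Adjusted over the list alone, 2 adhesion genes rose and 2 fell.

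Neuropeptide genes went both ways (list adjusted p = 0.168). Vip and Cartpt (-0.79, SE 0.11) fell, and Gal, which encodes galanin, rose (0.82, SE 0.14); 11 of 14 members were not called. Sst was at -0.61 (adjusted p = 0.089). Adjusted over the list alone 4 fell and 2 rose. The call of Cartpt was lost without wildtype 2 or 3 (adjusted p = 0.099 and 0.091), and that of Gal without any array but wildtype 1 (0.065 to 0.155).

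Hypoxia and glycolysis genes fell (adjusted p = 0.0096; adjusted p = 0.57 with an estimated correlation), with 11 of 12 members below 0. Bnip3, a mitophagy receptor, was the only one called (-0.50, SE 0.075), over all genes as well as adjusted over the list alone, and Hk2 was at -0.28. The call of Bnip3 was lost without any array but knockout 2 (adjusted p from 0.090 to 0.145). With the main settings oxidative phosphorylation was the only list that rose (adjusted p = 0.047; adjusted p = 0.68 with an estimated correlation). Of its 20 members 17 were above 0 and none was called by either adjustment, with Ndufa2 at 0.27, Ndufb3 at 0.22 and Ndufa4 at 0.16. This list passed in only 6 of 18 alternatives. Its call was lost without any single array but knockout 3 (adjusted p from 0.054 to 0.197), without both lens-rich arrays (0.102), with the lens covariate (0.054), with a log2 floor of 6 (0.069), with a second quantile normalization (0.104), with the replicate number as a block (0.058) and with fry (0.199).

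Stress and injury lists did not pass the threshold with the main settings on all 6 arrays. In Muller gliosis and retinal injury (adjusted p = 0.711) Gfap was at 0.44 (adjusted p = 0.195) and Lcn2 at -0.45 (0.104), and Lcn2 alone fell adjusted over the list alone. Among p53 targets (0.472) Cdkn1a, an inhibitor of the cell cycle, was at 0.44 (adjusted p = 0.051) and rose adjusted over the list alone. In the neuronal injury list (0.120, and 0.04998 with no filter on dim probe sets) Gal rose. In the cell cycle list (0.425) Plk1 was at 0.86 (adjusted p = 0.084) and rose adjusted over the list alone. Complement (0.663), interferon-stimulated genes (0.894), MHC class I (0.424), cell death (0.574), ER stress (0.501), retinal progenitor factors (0.660), circadian clock (0.306), immediate early genes (0.692) and cholesterol synthesis (0.168, and 0.048 without knockout 1) had no called member. The interferon list and the imprinted gene list had medians of -0.01 and -0.02 while their tests pointed up.

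Lists tied to Atrx held single called genes. Of the imprinted genes (list adjusted p = 0.584) Nnat rose (0.75, SE 0.085), on both of its probe sets in size (0.75 and 0.66), while Mest was at 0.31 and Zdbf2 at 0.35; these 3 rose adjusted over the list alone. Of the ancestral pseudoautosomal genes (0.528) Csf2ra fell (-0.86, SE 0.10) and Mid1 was at 0.49; adjusted over the list alone 1 fell and 1 rose. Without wildtype 2 the calls of Nnat (adjusted p = 0.065) and Csf2ra (0.055) were lost. No member of the ATRX and H3.3 chromatin partners (0.472) or of the alpha-globin cluster (0.744) was called.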

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

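The comparison of all probe sets was planned, and no test in this part was chosen after the result was seen. Probe sets without a single gene symbol, which the comparison of genes did not use, held differences between knockout and wildtype. Of 9472 past the same brightness filter, 29 were called when all 25961 probe sets were tested together. Over all 25961, 74 were called, a similar share, so these probe sets showed no clear excess. Of the 29, 25 rose and 4 fell, and 27 have no symbol in the annotation used here while 2 have several. Their median absolute log2 change was 1.19. No explanation was tested for them.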

How the results depend on the processing

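Leaving out the 2 lens-rich arrays and the lens covariate were chosen after seeing the data; the other alternatives were planned. The cause of each shift was not tested unless fewer genes or arrays are named. Against 129 genes called (75 rose, 54 fell), the counts were 74 (43 and 31) with no filter on dim probe sets, where more genes were tested, 209 (118 and 91) with a log2 floor of 6, where fewer were, and 282 (165 and 117) with an intensity trend and robust spread. Without the 2 lens-rich arrays, hence with 4 arrays, they were 36 (20 and 16), and over all probe sets 74, of which 22 fell. A test without pooled spread called 1 gene, which rose, and 0 that fell, while limma called 129 on the same values, with 2107 at an unadjusted p under 0.05. With a fold of at least 1.5 added, 34 genes fell. Leaving out 1 array gave between 25 (without wildtype 2) and 141 genes, 17 to 64 that rose and 8 to 77 that fell. All 129 kept their direction in each case, as they must when the values of the 2 groups do not overlap. Atrx kept its log2 change of -0.53 with an intensity trend and passed the threshold there (adjusted p = 0.039; range over its alternatives 0.039 to 0.320), and ranged from -0.64 to -0.45 without single arrays. The 9 lists called became 0 with an estimated correlation and 0 with fry, and 5 (without wildtype 3) to 12 without single arrays. With an estimated correlation adjusted p was 0.569 for GABAergic amacrine and horizontal cells, 0.453 for glycinergic and starburst amacrine cells and 0.684 for glutamate receptors; with fry it was 0.143 for GABAergic amacrine and for horizontal cells, 0.055 for glycinergic and starburst amacrine cells and 0.264 for glutamate receptors. The 3 amacrine lists passed in the other 16 alternatives. Horizontal cells had adjusted p = 0.057 without the lens-rich arrays. Without single arrays horizontal cells ranged from 0.0060 to 0.152, glutamate receptors from 0.00089 to 0.126, GABAergic amacrine cells from 0.00031 to 0.018, glycinergic from 6.2e-05 to 0.0028 and starburst from 0.00058 to 0.016. The lens list turned from down to up and passed the threshold without wildtype 1 (adjusted p = 0.0040; up to 0.919 without another array), which leaves knockout 2 as the only lens-rich array. Averaging probe sets took Tceanc2 to 0.84 and Mef2c to -0.38 (adjusted p = 0.108). The labels number the replicates of both groups from 1 to 3 without saying that a number marks a litter. Deviations of same-numbered arrays from their group means correlated at -0.27, -0.38 and -0.06, and 0 of 3 arrays of either group correlated best with its own number. The highest correlation, 0.39, was that of knockout 2 with wildtype 1, the lens-rich arrays. Lens RNA can hide a litter effect in these values, so pairing by litter is neither shown nor excluded. With the replicate number as a block the count was 68 (40 and 28), with fewer residual degrees of freedom. Dim probe sets sit near background, where signal over background limits the folds seen.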

Other observations

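The tests on the lens pattern, on the genes still called with the lens score as a covariate and on equal loss of amacrine cells, the gene groups of the next paragraph, and the limits set on the germline and motile cilia tests for dim genes were chosen after the results were seen; the other tests were written before their own result was seen, on patterns already noticed.

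Of 6 tested genes of the cerebellin and C1q-like families, which encode secreted synaptic organisers, 5 fell; the families were picked after the called genes were seen, so this count is no test of a class. The 5 were Cbln4 (log2 change -0.88), C1ql2 (-0.79), C1ql1 (-0.76), Cbln1 (-0.66) and Cbln2 (-0.43), while Cbln3 was at 0.08, and C1ql3 and C1ql4 were not tested. The call of Cbln2 was lost without any one of the 6 arrays (adjusted p from 0.068 to 0.223), that of Cbln1 without knockout 1 or any wildtype array (0.060 to 0.093), that of C1ql1 without knockout 1 or wildtype 2 or 3 (0.080 to 0.105), that of Cbln4 without wildtype 2 or 3 (0.093 and 0.082) and that of C1ql2 without wildtype 2 (0.053). Without the 2 lens-rich arrays all 5 missed the threshold (0.065 to 0.198). Single genes with roles in mitosis or the cell cycle rose; they were picked from the called genes, so they are no test of a class, and the fixed cell cycle list was not called (adjusted p = 0.425). They are Cdk6 (1.02, SE 0.14), the spindle checkpoint gene Bub1b (0.87, SE 0.10), Haus8 (0.68, SE 0.091), Racgap1 (0.66, SE 0.076) and Kif22 (0.61, SE 0.088). Bub1b passed the threshold without any single array. The calls of Haus8 and Kif22 were lost without any array but knockout 2 (adjusted p from 0.051 to 0.109), that of Cdk6 without knockout 1 or any wildtype array (0.055 to 0.101) and that of Racgap1 without wildtype 2 or 3 (0.065 and 0.055). Without the 2 lens-rich arrays all 5 missed the threshold (adjusted p from 0.060 for Bub1b to 0.121 for Cdk6).

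Lens RNA was high on knockout 2 and wildtype 1, and tissue carried over in dissection may be the source but was not put to a test that could support it. All 12 lens genes with a mean of at least 8 on those arrays, 100 percent, were higher on both than on each other array, by a median of 5.34 on the log2 scale, but these genes were chosen on the same 2 arrays, so the count restates the pattern. With 1 array of each group high, genotype alone did not decide which arrays were high. The overlap of the groups (difference of list means -0.34) follows from the same 2 arrays, so a smaller genotype effect on lens genes stays open.

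Lens RNA was also weighed as the source of the 129 genes called between genotypes. With the lens score as a covariate 100 percent of them had the same direction at an unadjusted p under 0.05, but this held in all 17 settings compared, so it decides nothing. With that covariate 99 genes were called, and 93 of the 129 were among them, in a fit that called the lens term for 34 other genes. Over all 129, the log2 change with the covariate was 0.98 to 1.03 times that without it, and the lens term was called for 0 of them. With 1 lens-rich array in each group, the covariate could hardly shift a difference between the groups. Genes whose groups do not overlap could also hardly follow the lens score. These values show only that the lens score removed little of the 129 changes. They do not decide whether lens RNA was a source of them. For the 36 no longer called, the median absolute log2 change was 0.49 (median SE 0.081) before and 0.49 (0.088) after. Their calls ended (adjusted p up to 0.081) with a larger SE and 3 residual degrees of freedom in place of 4. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, called as many as 129 genes and the highest of the others called 0, but 10 splits are too few for a share under 0.05.

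Equal loss of all amacrine cells, as the only source of the marker fall, predicts 1 common log2 change of markers made by these cells alone. The 20 markers with a wildtype mean of at least 7, a cutoff set after the test was first written, did not share 1 log2 change (Cochran's Q across genes 239.57 on 19 degrees of freedom), and 14 of them had 95% intervals above the median of the called markers (-0.68). By the first wording these values count against equal loss. The spread across the 20 markers argues against equal loss as the only source of their changes. Limits remain, as that median comes from genes selected for their fall and none of the 14 was called. Some of the markers, such as Pax6 and Tcf4, are also made by other cells. A second version, equal loss of all amacrine cells judged on the called markers alone, was written when their values were known and its outcome could be foreseen: the 7 differed too (Q 50.2 on 6), but 0 of them had a mean of at least 7 in both groups, and probe background can make equal falls look unequal. The mean change of the 7 was -0.97 without the lens-rich arrays and -0.86 with them. As the 7 were chosen as called on all 6 arrays, leaving 2 out could hardly shrink that mean, so this decides nothing about lens RNA. The covariate values above cover these 7 and decide no more for them. Death of some amacrine types and lower transcription within surviving cells both stay open.

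Other patterns were tested on gene classes. The 4 other tested ciliary body genes had a median log2 change of -0.098. Wfdc1 (0.12) and Zic1 (-0.01) had 95% intervals above -0.3, but Otx1 (-0.19) and Col9a1 (-0.26) did not, so less ciliary epithelium stays open as a source of the falls of Best2 (-1.20) and Optc (-0.44). The call of Optc was lost without any one of the 6 arrays (adjusted p from 0.065 to 0.200) and that of Best2 without wildtype 2 or 3 (0.061 for each). Beside the rise of Tex15 the median of 23 germline genes was -0.015, with all 23 under 0.3. Beside the rises of Wdr66 (1.01), Kif19a (0.95), Mlf1 (0.77) and Rfx2 (0.58) the median of 19 motile cilia genes was 0.0055, with Rfx3 at 0.25. The calls of Rfx2 (without any array but knockout 2, adjusted p from 0.072 to 0.115), Mlf1 (without wildtype 2 or 3, 0.055 and 0.050) and Kif19a (without wildtype 2, 0.051) were lost without single arrays. As first written, both medians would count against a rise of the class; but 18 of the 23 and 11 of the 19 had means below 5, where probe background hides small changes, and 0 and 1 had a mean of at least 7, so both stay open. Beside the rises of Zfp949 (1.17) and Zfp472 (0.82, its call lost without wildtype 2 at an adjusted p of 0.065), 332 genes named Zfp plus digits were shifted up by a median of 0.056 (camera p = 0.000948 with the preset correlation, p = 0.306 with an estimated correlation), which is far below either rise. Genomic span and log2 change correlated across genes at a Spearman rho of -0.065, less than the highest size of 0.358 among the other 9 splits. That split had both lens-rich arrays on the same side, but a split with 1 on each side reached -0.322. Genes are not independent replicates. The called genes that fell had a median span of 56.8 kb, those that rose 29.2 kb and all tested genes 20.9 kb. These medians were not tested.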
